A study of Solanum lycopersicum with 12 samples.

How the data were processed

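Transcript abundance was measured by RNA sequencing in 12 libraries from roots of tomato (Solanum lycopersicum, cultivar Marmande). Seedlings grown in hydroponic culture were 4 days old when they received zoospores of the oomycete Phytophthora cinnamomi, a soil-borne root pathogen, from a stock of 10000000 zoospores per ml. Control seedlings received water. Roots were collected at 3 and 7 days post inoculation (dpi). The libraries form 4 groups of 3: mock at 3 dpi, inoculated at 3 dpi, mock at 7 dpi and inoculated at 7 dpi. Groups were taken from the sample titles, since the treatment field of the labels reads mock for all 12 libraries while 6 titles and descriptions name the oomycete. The labels number the replicates 1 to 3 in each group and do not say whether they came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical. All 12 libraries carry the same batch label.

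Per the labels' protocols, RNA was extracted with a kit from frozen tissue and 1 ug of total RNA entered an Illumina TruSeq RNA library preparation. The submitters' processing notes name cutadapt, HISAT2, StringTie and featureCounts without versions, roles or order. The genome build, the annotation, the handling of reads with several alignments and the strand setting of the counting are not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical gene copies therefore cannot be assigned with certainty. The deposited table, 1 column per library, holds raw read counts per gene as the authors made them, with no normalization. It lists 35825 identifiers, of which 34658 have the Solyc form used for tomato loci and 1167 the ENSRNA form that Ensembl uses for non-coding RNA. No row is a total or an unassigned class, and 0 columns lacked a sample.

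Neither the table nor the reference table used here pairs these identifiers with gene names: 0 of the 35825 identifiers matched a locus tag, symbol, synonym or accession. The design, the alternatives, the rule for printed genes and 43 gene lists were fixed before the data were examined. The lists (pathogenesis-related proteins, pectin enzymes, hormone pathways, cell wall, hypoxia, photosynthesis and others) were defined by product names and could not be matched, so 0 lists were tested and pectin genes were not analysed here. Chromosome numbers come from the digits that the Solyc form places before the letter g, and gene order from the locus number after it. No coordinates were used.

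Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 20931 genes holding at least 99.89% of the counts of each library. Library sizes were scaled by TMM factors. A quasi-likelihood model with 1 coefficient per group and robust dispersion was fitted to all 12 libraries, and 5 contrasts were tested: inoculated minus mock at 3 dpi, the same at 7 dpi, the difference of these effects, and 7 minus 3 dpi in mock and in inoculated roots. P-values were adjusted by the Benjamini-Hochberg method over the 20931 genes, with a threshold of 0.05. Standard errors of log2 fold changes were obtained as the log2 fold change divided by the square root of the F statistic. Normalised expression is given as CPM, read counts scaled by TMM to a common library size. Gene sets were tested with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01 and with an estimated one, and with fry.

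The rule for genes to be named took the largest changes among called genes whose 3 values per group did not overlap and whose mean reached 5 CPM in the higher group, provided that the gene had a name. As no gene had one, the name criterion was dropped and 2 identifiers per direction were printed, those with the largest changes at 3 dpi. Other parts of the rule, which asked for more genes in this and the other comparisons or for members of the lists, were not applied. The summaries by expression level, chromosome, neighbouring genes, score and confidence interval, and the tests of the 3 dpi sets at 7 dpi, were chosen after the data had been seen.

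Total counts ranged from 7931729 to 12533878 per library. The edgeR fit was tested on simulated data: in 5 tables per comparison, counts were drawn for the 20931 genes from the observed means, library sizes and dispersions, and 200 genes were changed. For the 3 dpi comparison, 4.82% of the genes changed 1.5-fold, 40.5% of those changed 2-fold and 83.7% of those changed 4-fold were called, with at most 10 false calls per table. For the 7 dpi comparison, the values were 4.8%, 42.6% and 79.8%, with at most 7 false calls. The adjusted threshold is stricter when few genes change, so these shares do not give the power where more genes changed. Each gene was drawn independently of the others. The false calls therefore do not cover differences between libraries that many genes share, and may be more numerous in the real data. Replicates were compared by a chi-square of their counts over genes with at least 10 reads in the pair. The statistic was 8.77 to 40.3 per degree of freedom, so none of the replicate pairs within a group looked like 1 library deposited a second time.

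Alternatives were the RLE factors of DESeq2 or library size alone in place of TMM, no filter on low counts, DESeq2 1.42.0, a fit of only the groups compared, a replicate block, a minimum log2 fold change of 1, and each library left out in turn. The share of counts on ENSRNA identifiers as a covariate (its log2, centred) and a table without those identifiers were added after seeing the data. Replicate numbers are shared by the 4 groups. Deviations from the group mean correlated, across genes, between -0.22 and 0.39 for same-numbered libraries of different groups, and exceeded 0.1 in 3 of 18 such pairs. For differently numbered libraries the range was -0.4 to 0.36, and 6 of 36 pairs exceeded 0.1. The numbers were therefore not treated as pairing the libraries.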

Results

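Root transcriptomes of tomato seedlings inoculated with P. cinnamomi zoospores or with water were compared at 3 and 7 dpi, with 3 libraries per group. The study's title concerns the part that pectin plays in this interaction; pectin genes could not be picked out by name and were not analysed here. Libraries held 7931729 to 12533878 counts, and reads were found for 23571 to 24252 of the listed genes per library. The 10 most abundant genes of a library took 1.88% to 2.8% of its counts. The ENSRNA identifiers, which Ensembl gives to non-coding RNA, took 0.192% to 0.874%. Their mean share was 0.362% ± 0.233 (SD, n = 3) in mock and 0.262% ± 0.108 in inoculated roots at 3 dpi, and 0.458% ± 0.271 and 0.555% ± 0.331 at 7 dpi. These ranges overlap between all groups.

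At 3 dpi the inoculated libraries stood apart from the others on the first principal component of log2 CPM, which held 34.4% of the variance. Their scores were -29.4, -65.6 and -92.3, against -9.8, 5 and -7.2 in mock roots of the same day. At 7 dpi the inoculated libraries (30.4, 11.3 and 39.6) lay among or below the mock libraries (42.8, 48.2 and 26.8). Correlations of log2 CPM across genes, which are not independent replicates, were 0.944 to 0.981 between inoculated replicates at 3 dpi and 0.914 to 0.965 between mock and inoculated libraries of that day. At 7 dpi they were 0.942 to 0.97 between mock and inoculated libraries, about the range within the groups (0.951 to 0.978 in mock, 0.958 to 0.961 in inoculated). Mock replicate 3 and inoculated replicate 2 at 7 dpi were each closer to one another (0.97) than to any library of their own group. At 3 dpi, inoculated replicate 1 was closest to inoculated replicate 2 (0.975). It correlated more with mock replicates 2 and 3 of that day (0.964 and 0.965) than with inoculated replicate 3 (0.944).

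**Figure D1:**
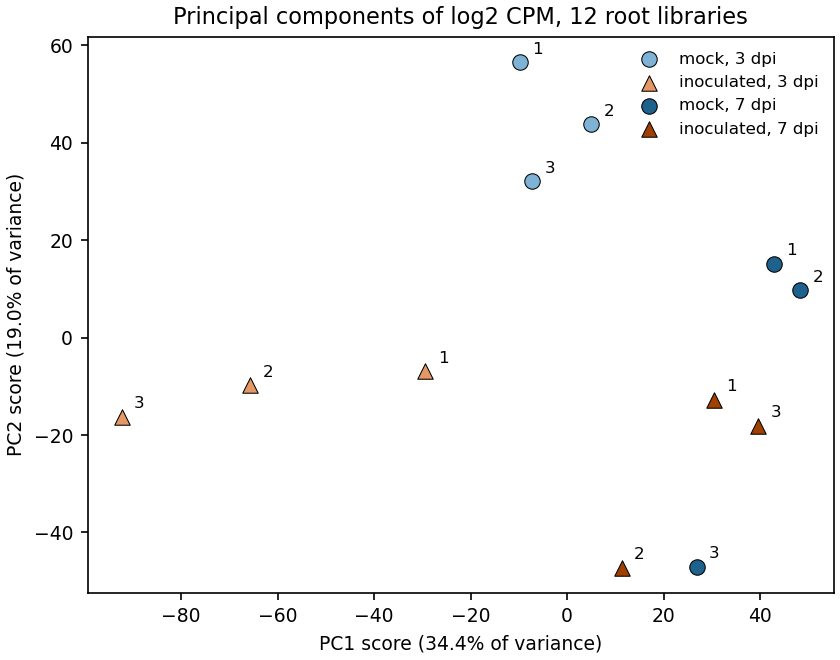
Scores of the 12 libraries on the first (x axis, 34.4% of variance) and second (y axis, 19% of variance) principal components of log2 CPM, with replicate numbers beside the points. The 3 inoculated libraries at 3 dpi (light triangles) lie at -29.4 or below on the first component, and the 7 dpi groups intermingle.

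The first comparison asked which root transcripts differed 3 days after contact with the oomycete. Between inoculated and mock roots 1898 of 20931 tested genes differed (9.07%): 655 rose and 1243 fell in inoculated roots (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among the called genes, falls were more numerous but smaller. The median log2 fold change was 1.02 among risen and -0.82 among fallen genes, and changes of at least 4-fold were found for 115 risen and 11 fallen genes. At least a 2-fold change was found for 341 risen and 354 fallen genes. The share that fell was higher among abundant transcripts, a difference that was not tested. Of the genes, 290 of 2309 with a mean above 100 CPM fell (12.6%) and 67 rose (2.9%), whereas among 6122 genes of 1 to 10 CPM 110 fell (1.8%) and 191 rose (3.12%). More reads also make a given fold easier to call, so neither these shares nor the medians of the called genes are adjusted for power.

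Among called genes whose libraries did not overlap between the groups and whose mean reached 5 CPM in the higher group, those with the largest changes are given. Of the risen ones, Solyc08g005620.3 went from 0.127 ± 0.22 CPM in mock to 5.76 ± 2.6 CPM in inoculated roots (SD, n = 3; log2 fold change 5.64, SE 1.22, edgeR adjusted p = 0.022). Its mock libraries held 3 reads in all against 196, a ratio of 55.7 with a 95% exact binomial interval of 18.8 to 272 that covers counting error only. All 3 of these reads came from mock replicate 3, and without that library the fitted log2 fold change was 8.93, a value set by the prior count against mock libraries at 0. Solyc04g081130.1 rose from 0.739 ± 0.487 to 18.4 ± 9.52 CPM (log2 fold change 4.66, SE 0.92, edgeR adjusted p = 0.017). Of the fallen ones, Solyc02g086820.3 was an abundant transcript that went from 1140 ± 460 to 253 ± 184 CPM (log2 fold change -2.17, SE 0.56, edgeR adjusted p = 0.04). Solyc00g006805.1 fell from 6.44 ± 2.15 to 1.34 ± 1.15 CPM (log2 fold change -2.22, SE 0.51, edgeR adjusted p = 0.025). The digits of the identifiers place these genes on chromosomes 8, 4 and 2 and, for the last, on sequence not assigned to a chromosome (00). The table and reference used here give no names for them. Without mock replicate 2, inoculated replicate 2 or inoculated replicate 3 of that day, none of the 4 passed (edgeR adjusted p from 0.064 to 0.11, 0.076 to 0.14 and 0.067 to 0.094). Solyc08g005620.3 also missed the threshold without mock replicate 1 (0.074), Solyc00g006805.1 without mock replicate 3 (0.057), and Solyc02g086820.3 without mock replicate 1 (0.052) or 3 (0.083). With all libraries, Solyc02g086820.3 missed it with the replicate block (0.053), with only the groups compared in the fit (0.079), without the filter on low counts (0.061) and with the ENSRNA covariate (0.064), and Solyc00g006805.1 with only the groups compared (0.053).

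**Figure D2:**
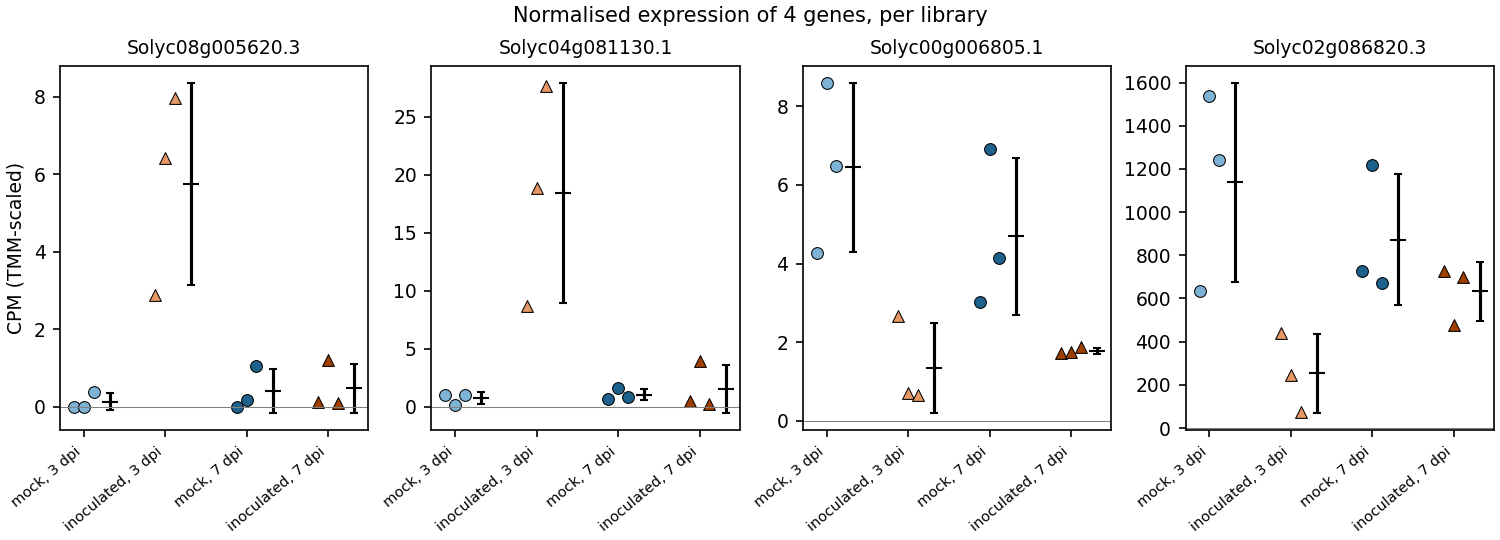
TMM-scaled CPM (linear y axes, one panel per gene) of the 4 printed genes in each library (points), with the group mean and SD (bar, n = 3) at the right of each group. At 3 dpi the inoculated libraries of each gene lie outside the range of the mock libraries, and at 7 dpi the mean ± SD of the risen genes is 0.473 ± 0.636 and 1.54 ± 2.1 CPM in inoculated roots.

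By chromosome, taken from the identifiers, the shares were similar in size. On each of the 12 chromosomes between 2.5% and 4.05% of tested genes rose and between 4.95% and 6.52% fell. The strongest departure was chromosome 8, where 61 of 1508 tested genes rose (4.05%, against 3.07% elsewhere; Fisher's exact test, two-sided, p = 0.046), which did not pass adjustment over the 26 tests of chromosome and direction (adjusted p = 0.7).

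The 3 dpi count depended on single libraries. It was 0 without inoculated replicate 2 (4276 genes at unadjusted p under 0.05), 54 without inoculated replicate 3, 197, 733 and 831 without mock replicates 2, 1 and 3 and 2396 without inoculated replicate 1. The median log2 fold change of the 1898 genes, signed by direction, was 0.85 (median SE 0.21) without inoculated replicate 2 and 0.79 (median SE 0.2) without inoculated replicate 3, against 0.86 (median SE 0.18) with all libraries, on which the genes were chosen. A fit of only the 3 dpi groups called 2433 genes (1111 rose, 1322 fell), of which 1504 were also among the 1898 in the same direction. The share of falling calls was 65.5% with TMM scaling, 52.5% with library size alone and 53.7% with DESeq2, which called 3205 genes (1483 rose, 1722 fell).

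The same comparison at 7 dpi asked whether the difference persisted. The edgeR test called 0 of 20931 genes. An unadjusted p under 0.05 was found for 1629 genes (776 higher, 853 lower in inoculated roots), against 1047 expected by chance. Of the 10 splits of the 6 libraries into 3 and 3, 5 gave at least as many such genes, the real one included. DESeq2 called 73 genes (53 rose, 20 fell). Values of the 4 printed genes at 7 dpi were a log2 fold change of 0.15 (SE 1.22, edgeR adjusted p = 0.98) for Solyc08g005620.3, 0.51 (SE 0.94, 0.92) for Solyc04g081130.1, -0.46 (SE 0.54, 0.87) for Solyc02g086820.3 and -1.4 (SE 0.51, 0.55) for Solyc00g006805.1. The 95% interval of the 7 dpi effect lay within a 2-fold change either way for 15252 genes (72.9%). Of the 695 genes called at 3 dpi with at least a 2-fold change, 382 (55%) had a 7 dpi interval that excluded a 2-fold change in the 3 dpi direction. Without mock replicate 3 the edgeR test called 26 genes (25 rose, 1 fell).

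The genes called at 3 dpi differed by little at 7 dpi. The 7 dpi libraries do not enter the 3 dpi contrast, but they share the estimate of dispersion that decided its calls. The 655 risen genes had a median log2 fold change of 0.14 at 7 dpi (quartiles -0.05 and 0.45), and 446 of them (68.1%) were higher in inoculated roots. The 1243 fallen genes had a median of -0.08 (quartiles -0.23 and 0.04), and 830 (66.8%) were lower. Relative to other genes, camera with a preset correlation placed the risen set higher (adjusted p = 8.5e-06) and the fallen set lower (adjusted p = 0.00046). Neither call held with an estimated correlation (adjusted p = 0.55 for both, estimated correlations 0.29 and 0.35), and fry of limma, which tests a set against no change and not against other genes, gave directional p = 0.4 and 0.46 and mixed p = 0.095 and 0.26. Across all tested genes the log2 fold changes at 3 and 7 dpi correlated with Pearson's r = 0.258 and Spearman's rho = 0.185, and across the 1898 genes called at 3 dpi with r = 0.463 and rho = 0.478. No library enters both effects, genes are not independent replicates, and no p-value is given. The correlation over all genes was 0.07 without inoculated replicate 2 at 7 dpi, 0.16 and 0.17 without mock replicates 1 and 2 at 7 dpi, and 0.13 without the filter on low counts. As 0 genes were called at 7 dpi, the overlap of calls could not be formed.

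A score per library, the mean log2 CPM of the 655 risen minus that of the 1243 fallen genes relative to mock roots at 3 dpi, was 2.08 ± 0.43 in inoculated roots at 3 dpi (SD, n = 3). It was chosen on these libraries there. At 7 dpi it was 0.36 ± 0.29 in mock and 0.63 ± 0.4 in inoculated roots, and the libraries overlapped, with 0.16, 0.23 and 0.69 against 0.66, 1.02 and 0.22.

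**Figure D3:**
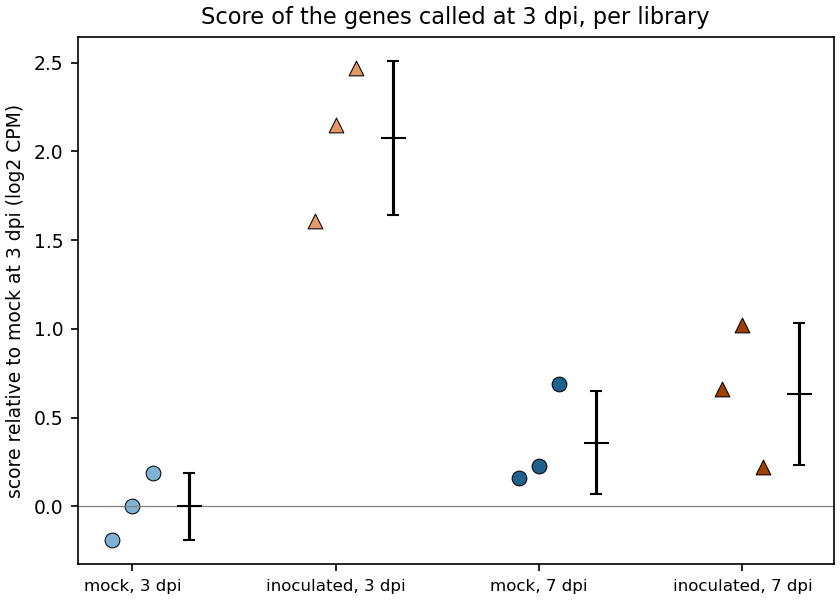
Score of the genes called at 3 dpi (mean log2 CPM of risen minus fallen genes, y axis, relative to mock at 3 dpi) for each library (points), with group mean and SD (bar, n = 3). Inoculated libraries at 3 dpi, on which the genes were chosen together with the mock libraries of that day, lie at 1.61 to 2.47, and all 7 dpi libraries lie at 1.02 or below.

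Whether the effect of inoculation differed between the times was tested as the difference of the 2 effects. The edgeR test called 0 genes. At unadjusted p under 0.05 there were 3323 genes, against 1047 expected by chance, and the smallest adjusted p was 0.11. DESeq2 called 603 genes, of which 447 had a more positive effect at 7 dpi. For the 4 printed genes the difference was -5.5 (SE 1.84, edgeR adjusted p = 0.2), -4.15 (SE 1.32, 0.19), 1.71 (SE 0.77, 0.31) and 0.82 (SE 0.72, 0.59), in the order in which they are listed for 7 dpi. The edgeR test therefore shows for no single gene that its response differed between the times. It called 2 genes without mock replicate 1 at 7 dpi and 1 gene each without inoculated replicate 1 at 3 dpi and without inoculated replicate 2 at 7 dpi, each with a more positive effect at 7 dpi.

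Changes with time in roots without the oomycete serve as background. Between 3 and 7 dpi 665 genes changed in mock roots, of which 307 rose and 358 fell (edgeR, adjusted p under 0.05). In inoculated roots 2573 genes changed, of which 1302 rose and 1271 fell. With library size alone as the scaling, 969 rose and 1660 fell in inoculated roots (63.1% falling, against 49.4% with TMM). The mock count was 240, 172 and 309 without replicates 1, 2 and 3 of 3 dpi and 390, 327 and 188 without those of 7 dpi. The inoculated count was 680 and 871 without replicates 2 and 3 of 3 dpi and 1212 and 1157 without replicates 1 and 3 of 7 dpi. DESeq2 called 1717 genes in mock roots, a fit of only the groups compared 202 in mock and 1454 in inoculated roots, and a fit with the ENSRNA share as a covariate 1248 in inoculated roots. Of the 307 genes that rose in mock roots, 196 (63.8%) also rose in inoculated roots, where 19.1 would be shared by independent lists (Fisher's exact test, one-sided, p = 3.5e-160). Of the 358 that fell, 100 (27.9%) also fell in inoculated roots, against 21.7 (Fisher's exact test, one-sided, p = 1e-39). The shared genes that went opposite ways numbered 3 and 1. No library is common to these contrasts, and the Fisher p-values treat genes as independent. Genes risen at 3 dpi had a median log2 fold change from 3 to 7 dpi of 0.06 in mock and -0.76 in inoculated roots, and genes fallen at 3 dpi of -0.33 and 0.39. The genes were chosen on the mock and the inoculated 3 dpi libraries, which enter the mock and the inoculated medians respectively, and the value that this choice alone would give was not computed.

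**Figure D4:**
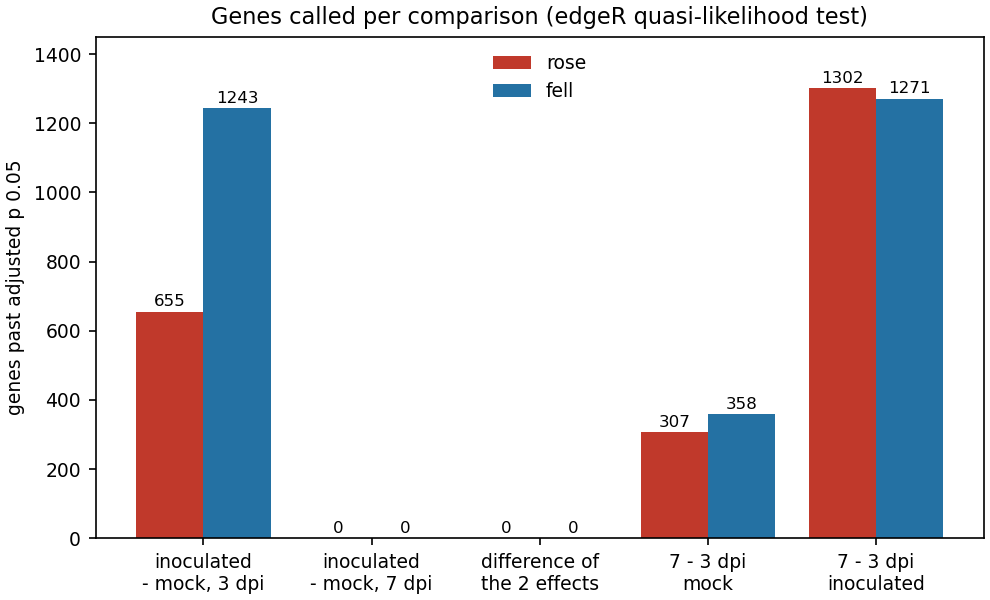
Number of genes that rose or fell past adjusted p 0.05 (edgeR, y axis) in each of the 5 comparisons (x axis). The bars show 655 and 1243 genes for inoculation at 3 dpi, 0 for inoculation at 7 dpi and for the difference of the effects, 307 and 358 for time in mock roots and 1302 and 1271 for time in inoculated roots.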

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

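The ENSRNA covariate and the removal of ENSRNA identifiers were chosen after seeing the data. Counts of called genes stayed within 1.5 times the reported ones with RLE factors, library size alone, no filter, the replicate block and removal of ENSRNA identifiers, in the comparisons where these were run. DESeq2 moved 4 counts: 3205 genes for inoculation at 3 dpi, 73 at 7 dpi, 603 for the difference of the effects and 1717 for time in mock roots. A minimum log2 fold change of 1 gave 695 genes at 3 dpi, 324 for time in mock and 1141 for time in inoculated roots. A fit of only the groups compared gave 202 and 1454 genes for time in mock and inoculated roots, and the ENSRNA covariate gave 1248 for time in inoculated roots. The cause of the shifts with DESeq2 and with the covariate was not tested, nor that of the shifts with the smaller fit, which called more genes for inoculation at 3 dpi (2433; 1111 rose, 1322 fell). The fold minimum selects among the same calls. Leaving out each library in turn gave 0 to 2396 genes for inoculation at 3 dpi, 0 to 26 at 7 dpi, 0 to 2 for the difference of the effects, 172 to 390 for time in mock and 680 to 3299 for time in inoculated roots. The single libraries behind these limits were inoculated replicates 2 and 1 at 3 dpi, mock replicate 3 at 7 dpi (26 genes), mock replicate 1 at 7 dpi (2 genes), mock replicate 2 at 3 dpi (172), mock replicate 1 at 7 dpi (390), inoculated replicate 2 at 3 dpi (680) and inoculated replicate 2 at 7 dpi (3299). The correlation of the 3 and 7 dpi effects, 0.26, became 0.13 without a filter and 0.46 over genes called at either time, and ranged from 0.07 (without inoculated replicate 2 at 7 dpi) to 0.36 (without mock replicate 3 at 7 dpi). The replicate numbers were not treated as pairing the libraries. Of 12 libraries, 6 correlated best with their own number, so a pairing is not excluded. A fit with the replicate block gave 1854 genes for inoculation at 3 dpi, 0 at 7 dpi and 0 for the difference. It gave 507 for time in mock and 2361 for time in inoculated roots. The printed genes kept their direction at 3 dpi in all 14 alternatives each and lost the threshold in 4 (Solyc08g005620.3, adjusted p 0.0011 to 0.086), 3 (Solyc04g081130.1, 1.1e-05 to 0.076), 9 (Solyc02g086820.3, 0.00063 to 0.14) and 5 of them (Solyc00g006805.1, 9e-04 to 0.11). At 7 dpi, where none passed, Solyc08g005620.3 turned to -0.37, -0.23 and -1.86 without mock replicates 1 and 2 and inoculated replicate 2, and Solyc04g081130.1 to -1.67 without inoculated replicate 2; with single libraries left out they reached 2.13 and 1.04 at the other end. Tables were simulated at this depth and spread with 200 genes changed. Of those changed 1.5-fold, 4.82% were called at 3 dpi and 4.8% at 7 dpi. The data held 1898 calls at 3 dpi, where the adjusted threshold is less strict, so recovery there may be higher. The alternatives for gene lists were not run, since no list could be matched.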

Other observations

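The tests of splits for the 3 and 7 dpi comparisons, of left-out pairs at 3 dpi, of the spread and label exchange at 7 dpi and of pairs 5 places apart were chosen after their results had been seen. For the difference of the effects, the number of splits drawn was lowered for computing time after the result of a larger draw had been seen.

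Genes that rose at 3 dpi lay next to one another more often than shuffled calls. In identifier order, 48 directly adjacent pairs rose together, where shuffling calls 2000 times within chromosome and expression class gave 15 (ratio 3.2, permutation p = 5e-04, the smallest that 2000 shuffles can give, adjusted p = 0.0038 over 30 tests). For fallen genes there were 77 pairs against 57.2 (ratio 1.35, adjusted p = 0.015). The risen genes formed 41 runs of 2 or more neighbours, holding 89 genes, with the longest of 5 genes on chromosome 3. The fallen genes formed 75 runs, holding 152 genes, with none longer than 3. In the time comparison of inoculated roots adjacent pairs were in excess (permutation test, adjusted p = 0.0038 for both directions). There were 90 against 60.8 for risen (ratio 1.48) and 98 against 56 for fallen genes (ratio 1.75). That comparison shares the inoculated 3 dpi libraries with the 3 dpi comparison, so it is not a separate observation. In mock roots the excess did not pass (permutation test, adjusted p = 0.3 and 0.25). The pairs there were few, 6 against 3.39 (ratio 1.77) and 8 against 4.62 (ratio 1.73). As the ratios were of similar size, an excess particular to inoculated roots is not shown. A candidate explanation is that tandem copies of related genes respond together, and another is that reads are shared between adjacent genes. Pairs 3 places apart rose together 1.27 times as often as shuffled calls (18 pairs, adjusted p = 0.3), which shared reads between neighbours predict, as would small tandem groups. Pairs 5 places apart rose together 2.12 times as often (30 against 14.1, permutation test, adjusted p = 0.0038). The shuffles broke up adjacent pairs of calls, so the shuffled counts may vary too little. They therefore cannot decide whether reads shared between direct neighbours lie behind this excess. The excess has no bearing on the adjacent pairs. At 3 dpi risen pairs 4 places apart were at 0.843 (12 against 14.2) and fallen pairs 5 places apart at 0.961. Risen pairs 2 places apart were at 1.57 (23 against 14.6, permutation test, adjusted p = 0.1). Over time, fallen pairs 2 places apart in inoculated roots passed (73 against 54.1, ratio 1.35, adjusted p = 0.042), and risen pairs 5 places apart in mock roots did not (7 against 3.23, ratio 2.17, adjusted p = 0.14). Without gene names or sequences, family membership was not tested, and reads shared among similar copies at a distance stay open.

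Of the 358 genes that fell with time in mock roots, 141 also fell on inoculation at 3 dpi, against 21.3 for independent lists, but both contrasts use the mock 3 dpi libraries. The overlap was mostly among falls: 17 of the 307 genes that rose with time also rose on inoculation, against 9.61, and 18 and 6 genes went opposite ways, against 18.2 and 11.2. The values for independent lists leave out the shared libraries, and the overlap that unchanged groups would give was not computed. Across genes the effects correlated with r = 0.157. Simulated unchanged groups gave 0.505 through those shared libraries. The simulation holds no real effects, whose variance lowers r, so these 2 correlations are not comparable. The covariance was 0.0488, against 0.0578 in simulation (0.0524 to 0.0613 over 100), a difference of -0.009. The mock libraries, 3 in all, cannot be split into parts of at least 2. Part of the 141 may come from the shared libraries; in the fit without mock replicate 2 at 3 dpi only 172 genes changed with time in mock roots.

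The difference between inoculated and mock roots at 3 dpi was weighed against chance, the non-coding RNA share and single libraries. The real split gave 1898 calls and the highest of the other splits 13 (1 of 10 reached the real count). These 10 splits are too few for a share under 0.05. The other splits mixed mock and inoculated libraries, so a group difference adds to their spread and lowers their calls. With the ENSRNA share as a covariate the median signed log2 fold change of the called genes kept 0.97 of its value, and 1342 genes were called. Those genes were chosen on the same libraries without the covariate, which favours a kept value. In genes chosen on 2 mock and 2 inoculated libraries (500 per direction), the left-out pair differed by 0.47 to 1.05 in average log2 change over 9 pairs (SD 0.22). Pairs with inoculated replicate 1 left out gave 0.47, 0.66 and 0.51, and the others 0.86 to 1.05. The pairs reuse the same libraries, so this SD is not a spread of independent values. As every left-out pair differed in the chosen direction, the values argue against 1 library alone setting the difference. Without inoculated replicate 2 the count of calls was 0 while the median signed log2 fold change of the 1898 genes, chosen with that library among the 6, was 0.85 (median SE 0.21) against 0.86 (0.18). Inoculation, the variable of the design, stays open as the explanation.

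The small difference at 7 dpi may reflect a weaker response, a larger spread or exchanged labels. Genes were chosen in turn on 2 mock and 2 inoculated 3 dpi libraries (500 per direction). They were scored as the average log2 change in the left-out pair and in each pair at 7 dpi. The left-out pairs differed by 0.47 to 1.05 and the 7 dpi pairs by -0.21 to 0.44. Means over the 7 dpi pairs were 0.14 to 0.19. For these genes this argues against spread alone hiding an effect of the 3 dpi size, by a narrow margin for single pairs. An effect of that size in other genes at 7 dpi would not enter the score, so spread is not excluded there. The median SD of log2 CPM within groups, over 20258 genes, was 0.189 in mock and 0.169 in inoculated roots at 3 dpi. At 7 dpi it was 0.204 and 0.218. No exchange of 1 mock and 1 inoculated library at 7 dpi raised the mean difference above 0.29. In the genes chosen at 3 dpi a single exchange would therefore not restore the 3 dpi size. A weaker response at 7 dpi stays open, as does infection that differed between the cultures, which was not tested. Exchanged labels beside a weaker response are not excluded. By genes at unadjusted p under 0.05, 5 of the 10 splits of the 7 dpi libraries reached the real 1629, the real one included. The highest other split had 2649. Although 10 splits are too few for a share under 0.05, the real grouping did not stand out by this count. The highest split, mock replicates 1 and 2 with inoculated replicate 1 against the rest, called 118 genes where the real one called 0. It equals an exchange of mock replicate 3 with inoculated replicate 1, whose mean difference in the 3 dpi genes was 0.11 to 0.17. These calls point to a structure of the libraries other than their labelled groups. Whether exchanged labels are behind it is not settled.

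For the difference of the effects, 5 of 60 splits drawn within each time, out of 200, had as many genes at unadjusted p under 0.05 as the real 3323, the real one included, with 6321 in the highest other. All 5 kept the real groups at 3 dpi and so carry the difference of that day, so these splits do not settle whether chance accounts for the real count; the splits that did not keep those groups reached at most 2493. The 7 splits that kept them called between 0 and 3012 genes, so with the 3 dpi groups fixed the calls changed with the grouping at 7 dpi. For time, 1 of 10 splits reached the real count in mock roots (665, highest other 0) and 1 of 10 in inoculated roots (2573, highest other 0), which is too few splits for a share under 0.05. The other splits mixed libraries of both days, so a change with time adds to their spread and lowers their calls.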
